A study of Solanum lycopersicum with 22 samples.

How the data were processed

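The samples were 22 scans of 11 single-channel oligonucleotide arrays, 1 array per plant, each scanned at a high and a low photomultiplier setting. Per the labels' protocols, total RNA was extracted with a CTAB buffer, amplified to antisense RNA and coupled to an Alexa Fluor dye. Each scanner file holds, per the file headers, the mean, median and standard deviation over the 4 to 8 spots of each probe, where the value of a spot is its foreground median intensity. These intensities are linear, as the authors' scanner software wrote them, and run from a floor of 1 to a ceiling of 65535. They have no background column, and the scanner and software settings are not given in the sources used here.

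The authors' value table of the whole series holds log2 intensities. Set against the scanner files, 18 of its 22 columns equal the log2 of that scan's own median intensity plus 1 constant per column, with probes whose spots varied by a coefficient above 0.5 left blank. Between 4128 and 9009 of the 20201 probes are blank per column, and column medians run from 7.48 to 9.80. The other 4 columns differ from their own scanner file beyond a constant. They belong to the high scan of IL7-3 replicate 1 of 2007 and the low scans of M82 replicate 6 and IL7-3 replicates 5 and 6 of 2008, and the table's column for the low scan of M82 replicate 6 equals the file of that plant's high scan. What the column constants were set to stays unknown. The value table served only as an alternative source of values.

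For the main values, the mean over spots was taken to log2, the 20201 gene probes were quantile normalized between plants separately within the high and the low scans, and both scans of a plant were averaged to 1 replicate. No background was subtracted and no dim probes were removed. The 42 spike probes and 54 factory probes, of which 35 are negative controls, stayed out of the normalization and the tests. The detection limit of a scan was the 95th percentile of its negative controls. A plant counted as above the limit where both scans were above it, and as below it where both were not. For a probe below the limit in a whole group, or in some M82 plants of a probe higher in IL7-3, a fold is given as "at least": the bright group's mean against the dim group's mean, with each dim plant at the higher of the probe's own value and the lowest normalized value among probes above the limit in that scan, with both scans of a plant averaged first. Of the 25 such probes among the lower ones, 10 had a bound of 2-fold or more, the highest being 7.85-fold, and 8 had none above 1. A p-value given beside an "at least" fold tests the fitted difference and not the bound.

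The labels group the samples by line and trial year (M82 2007, n = 3; IL7-3 2007, n = 2; M82 2008, n = 3; IL7-3 2008, n = 3), and the plants are separate plants. Identical median values above the floor made up at most 0.812% of probes between any 2 scans, so no scan file is a copy of another. The high and low scans of the same array also stay under that share. The measure therefore cannot show whether an array was entered again at another scanner setting. One limma model over all 11 plants estimated the 4 group means and a shared spread. The contrasts were the mean of both within-year line differences, the line difference in each year, the difference between those, and the mean of both within-line year differences. Adjusted p-values are Benjamini-Hochberg values over all gene probes, with a threshold of 0.05. The tests, the alternatives and the rule for named probes were fixed before the data were examined. Since no table names the probes' genes, the rule gives probe identifiers, at most 2 that rose and 2 that fell, those with the largest log2 difference past the threshold and in the same direction in both years. The remaining probes of counts of 5 or fewer were named after their values were seen. The year has no independent replicate, and year cannot be told apart from any step of labelling or scanning that followed it.

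Gene list tests and a test of chromosome 7, where the name of the line places the donor segment, had been prepared but could not be run: 0 of the 20201 contig identifiers matched the gene table used here, and no genome sequence was used. The 26 gene lists written in advance, among them markers of seed, locular tissue, cuticle, photosynthesis and heat shock, therefore have no result.

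The plants share replicate numbers across lines within a year. Over the 5 pairs with the same number, deviations from the group means correlated above 0.1 in 2 pairs, so the numbers were not taken to pair the plants. To describe the structure of the plants, they were clustered by 1 minus the correlation over the 6734 brightest probes (average linkage, 3 clusters), and principal components were taken over all probes. The clusters were defined from the data and are not groups of the study.

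The alternatives were the high or the low scans alone, the low scan where the high scan was saturated in any plant (354 probes), quantile normalization over all 22 scans, scaling to each scan's 75th percentile, cyclic loess, background correction from the negative controls (nec, offset 50), a filter on dim probes (10531 kept), the median in place of the mean over spots, the authors' value table (18096 probes with enough values), an additive and a year-free model, only the plants of a year, the replicate number as a block, array weights, a minimum log2 difference of 1, and each plant left out in turn. Alternatives added after seeing the data were cluster membership as a term, the larger cluster alone, that term without M82 replicate 5 of 2008, and the removal of 256 probes with short sequences (GCCTCC, CCGCCT, CTTCTCC or TCTTCTC) that differed between the clusters. Other splits of the plants into groups of the same sizes were refitted in 100 draws with random seed 1.

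The line fit was tested on simulated data with the real probe means and spreads, in which 200 of 20201 probes were changed. It recovered 1.23% of probes changed by a log2 difference of 1, 41.1% of those changed by 2 and 85.7% of those changed by 4, and called 6 of 20001 unchanged probes. Differences near 1 on the log2 scale are thus rarely found with 11 plants of such spread. The simulated plants had independent noise and no year effect, plant cluster, intensity floor or saturation, so the rates in the real data can differ. The computations used R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Biostrings 2.70.1 and, for the plots, Python 3.11.15 with matplotlib 3.10.9.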

Results

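Gene expression was measured in red-ripe fruit of tomato (Solanum lycopersicum) from the introgression line IL7-3 and from M82, the cultivated parent in whose background the line was made. An introgression line carries a chromosome segment of a wild donor species in an otherwise cultivated genome. The series describes IL7-3 as a line whose fruit contains more total phenolics than M82, and the comparison asks which transcripts differ between the fruits of the 2 lines. Each sample was the pooled outer fruit wall (epicarp and mesocarp) of 1 plant, without seeds, jelly, columella or placenta. The 2007 trial gave 3 M82 plants and 2 IL7-3 plants, and the 2008 trial gave 3 plants of each line. A further IL7-3 plant of 2007, which the series text implies, was not analysed here. Every array was scanned at a high and a low photomultiplier setting, so the 22 scans stand for 11 plants.

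The array carried 20201 gene probes of 35 to 40 bases, 1 per tomato transcript contig. The median probe intensity lay between 173.5 and 1142 in the high scans and between 31.4 and 212.0 in the low scans. Between 44.7% and 54.5% of the gene probes were brighter than the 95th percentile of the 35 negative control probes, which is used here as the detection limit. Both scans of a plant correlated across probes with r between 0.933 and 0.977, and different plants with r between 0.787 and 0.979. The number of arrays limits the precision of every value below. The files pair no probe with a gene name or a genome position, so probes are given by their identifier and sequence, and nothing is said about gene functions, pathways or chromosomes.

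The expression profiles did not sort by line or by year. The M82 plants of 2007 numbered 1 and 2 and IL7-3 replicate 1 of 2007 formed a cluster of their own. Over the 6734 brightest probes their correlations with each other were 0.833 to 0.896, against 0.528 to 0.637 with the 7 plants of the larger cluster. Replicate 5 of M82 in 2008 stood alone, with correlations of 0.583 to 0.722 to the larger cluster. The first principal component held 29.5% of the variance and the second 22.9%. Because the small cluster holds both lines, comparisons of the lines are given below also with cluster membership as a term in the model, an alternative chosen after the data were seen.

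**Figure D1:**
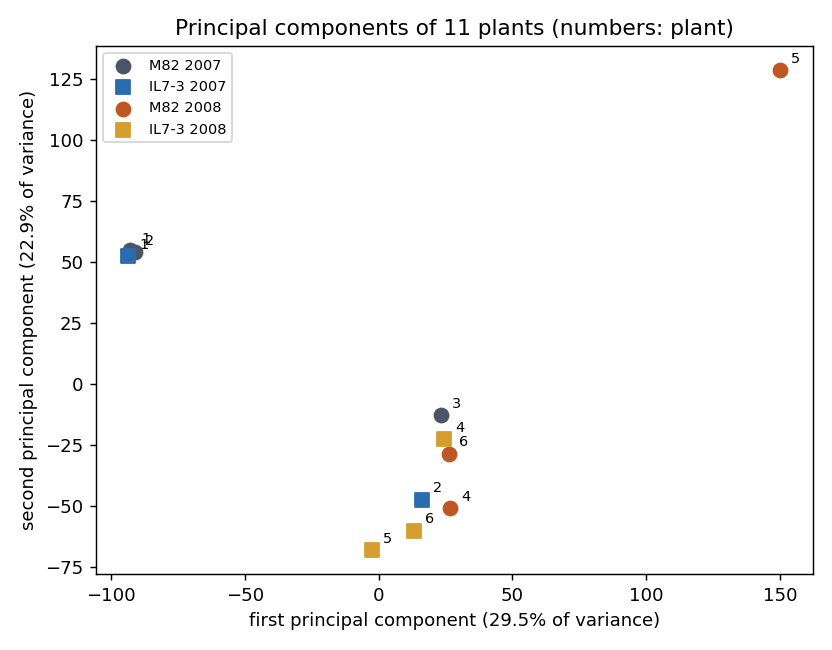
Positions of the 11 plants on the first (29.5% of variance) and second (22.9%) principal components of normalized log2 intensity over 20201 probes, with circles for M82, squares for IL7-3 and the plant number beside each point. The 3 plants at the left are M82 replicates 1 and 2 and IL7-3 replicate 1 of 2007, and the plant at the upper right is M82 replicate 5 of 2008.

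Averaged over both trials, 40 probes were lower and 3 were higher in IL7-3 than in M82 (limma, Benjamini-Hochberg adjusted p below 0.05 over 20201 probes). The counts were 31 and 1 with scaling to the 75th percentile, 36 and 3 with cyclic loess, and 10 and 1 with background correction from the negative controls. At an unadjusted p below 0.05 in limma there were 945 probes (4.68%), no more than the share that this threshold passes by chance. All 43 differed in the same direction in 2007 and in 2008. Since they were picked by the mean of both within-year differences, a shared direction was likely from the start and is no replication. Over all 20201 probes, every IL7-3 plant lay beyond every M82 plant in 154 probes (0.762%), an arrangement that chance gives to 0.433% of probes when 5 plants are set against 6. Of the 40 lower probes, 25 were below the detection limit in both scans of all 5 IL7-3 plants, 21 were above it in both scans of all 6 M82 plants, and 7 were both. In 23 of the 40, M82 had a mean log2 intensity in M82 above 8.86, the limit of the 6734 brightest probes in that line. Their median fitted log2 difference was -3.73, and -1.88 when the 25 probes below the limit were set to the smallest difference that the limit allows.

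The fitted difference was lowest for TC177079_695_40 (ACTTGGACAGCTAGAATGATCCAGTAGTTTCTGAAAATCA), an order that rests on values below the detection limit, since another lower probe has a higher bound of 7.85-fold. Its normalized log2 intensity was 10.53 ± 0.23 (SD, n = 3) in M82 and 3.32 ± 0.48 (SD, n = 2) in IL7-3 in 2007, and 10.63 ± 0.91 (SD, n = 3) in M82 and 2.75 ± 0.23 (SD, n = 3) in IL7-3 in 2008. It was above the detection limit in all 6 M82 plants and below it in all 5 IL7-3 plants, so it was at least 7.42-fold lower in IL7-3. The limma adjusted p of 4.5e-06 belongs to its fitted difference and not to that bound. TC170138_289_39 (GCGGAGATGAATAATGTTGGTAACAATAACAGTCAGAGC) behaved alike, with 9.12 ± 0.64 (SD, n = 3) in M82 and 3.18 ± 0.11 (SD, n = 2) in IL7-3 in 2007, and 9.96 ± 0.29 (SD, n = 3) in M82 and 2.85 ± 0.41 (SD, n = 3) in IL7-3 in 2008. This probe was at least 3.60-fold lower in IL7-3 (limma adjusted p = 4.5e-06 for the fitted difference). Within the small cluster, 2 M82 plants against 1 IL7-3 plant, TC177079_695_40 was at least 8.22-fold and TC170138_289_39 at least 2.78-fold lower in IL7-3. Within the larger cluster they were at least 7.49-fold and 3.48-fold lower in 2007, 1 plant against 1, and at least 9.22-fold and 4.59-fold lower in 2008, 2 M82 plants against 3 IL7-3 plants. With cluster membership as a term, the adjusted p was 1.3e-05 for both (limma).

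Among the 3 higher probes, TC170110_850_39 (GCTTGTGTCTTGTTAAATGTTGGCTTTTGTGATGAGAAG) was bright in both lines. Its normalized log2 intensity was 13.24 ± 0.38 (SD, n = 3) in M82 and 15.33 ± 0.62 (SD, n = 2) in IL7-3 in 2007, and 11.67 ± 1.28 (SD, n = 3) in M82 and 15.09 ± 0.36 (SD, n = 3) in IL7-3 in 2008. The fitted mean log2 difference was 2.75 (limma adjusted p = 0.039), against 2.64 with cyclic loess and 2.68 with scaling to the 75th percentile. Its high scan was saturated in all 5 IL7-3 plants, which holds the difference down in the values that use that scan. The low scans, saturated in 0 plants, gave a log2 difference of 3.11 for this probe. The limma adjusted p was 0.045 where low scans alone were used for probes saturated in any plant, and 0.081 where they were used for all probes. This probe's values are the same in both settings, and only those of other probes differ. TC174512_736_39 (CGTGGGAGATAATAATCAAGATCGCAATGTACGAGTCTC) was below the detection limit in all 3 M82 plants of 2007 and at least 5.05-fold higher in IL7-3 over both years (limma adjusted p = 0.019 for the fitted difference). Its normalized log2 intensity was 6.92 ± 0.42 (SD, n = 3) in M82 and 11.27 ± 1.49 (SD, n = 2) in IL7-3 in 2007, and 9.04 ± 0.03 (SD, n = 3) in M82 and 10.13 ± 0.36 (SD, n = 3) in IL7-3 in 2008. The fitted log2 difference was 4.35 in 2007 (limma adjusted p = 0.029) and 1.09 in 2008 (limma adjusted p = 0.61), so it did not pass in 2008 alone. The other riser, TC177287_1174_40 (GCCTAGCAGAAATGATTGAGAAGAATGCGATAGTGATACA), is named although its values had been seen. It was below the limit in 1 M82 plant of 2007 and at least 4.03-fold higher in IL7-3 (limma adjusted p = 0.038 for the fitted difference). With scaling to the 75th percentile and with cyclic loess, TC170110_850_39 had an adjusted p of 0.093 and 0.070, TC177287_1174_40 of 0.13 and 0.11, and TC174512_736_39 of 0.042 and 0.030. Over 29 alternatives the adjusted p of these probes reached 0.31, 0.23 and 0.22. With cluster membership as a term it was 0.049, 0.014 and 0.027.

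The falls of TC177079_695_40 and TC170138_289_39 passed the threshold in each of the 11 fits that left out 1 plant, with adjusted p up to 0.00011 and 0.00012. The rises lost the threshold in more of these fits, although their fitted differences stayed positive. The log2 difference ran from 2.19 to 3.24 for TC174512_736_39 and from 2.12 to 2.58 for TC177287_1174_40. TC174512_736_39 lost the threshold without IL7-3 replicate 2 of 2007 or without replicate 4, 5 or 6 of IL7-3 in 2008, with adjusted p up to 0.076 over the 11 fits. TC170110_850_39 kept it only without M82 replicate 4 or 5 of 2008 (2.49 to 3.11, adjusted p up to 0.22), and TC177287_1174_40 only without M82 replicate 2 or 3 of 2007 or M82 replicate 4 of 2008 (adjusted p up to 0.21). The count of 43 became 15 without IL7-3 replicate 1 of 2007, 20 without its replicate 2, 23 without IL7-3 replicate 5 of 2008 and 20 without its replicate 6. With cluster membership as a term, 40 probes were lower and 5 were higher, and 40 of the 43 probes remained.

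**Figure D2:**
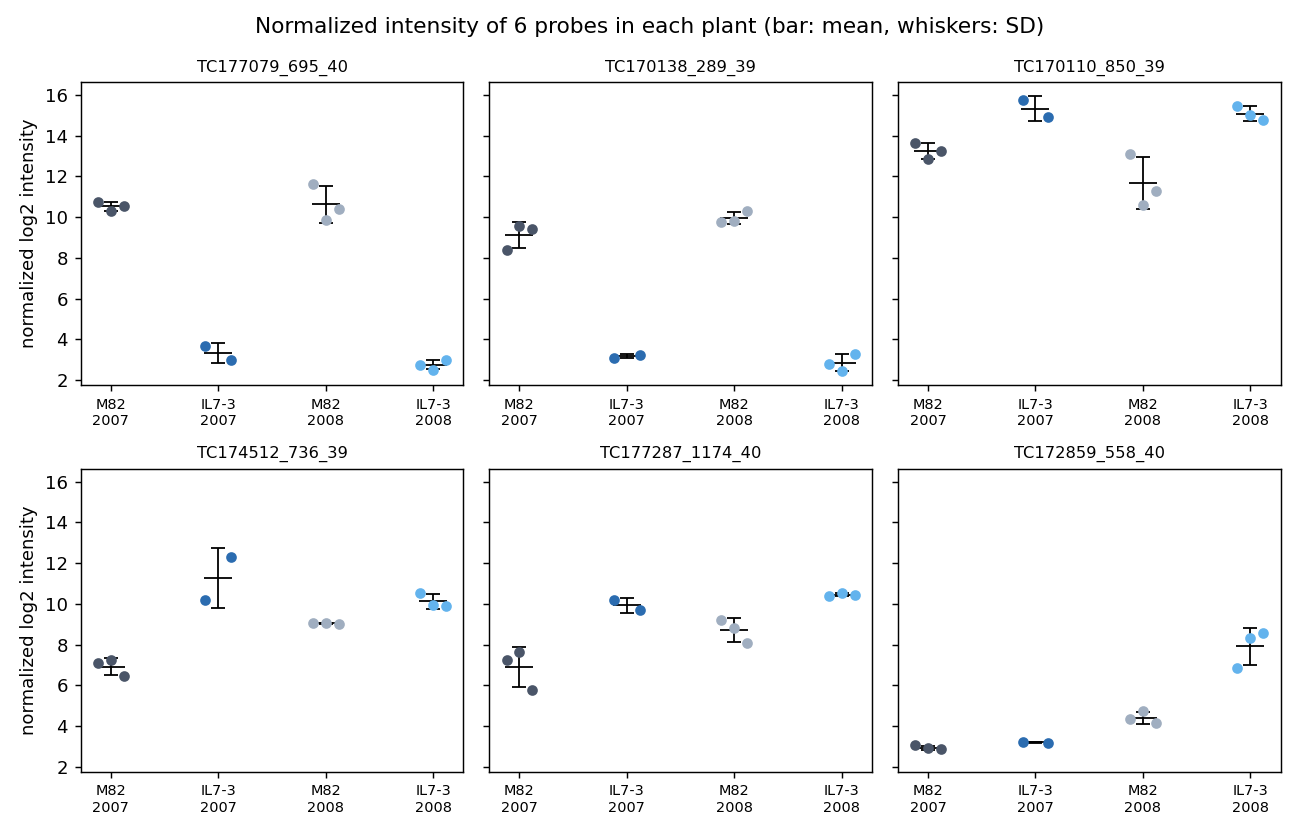
Normalized log2 intensity of 6 probes in each plant by line and year, with points for plants, horizontal bars for group means and whiskers for SD (n = 3, 2, 3 and 3). TC177079_695_40 and TC170138_289_39 lay above 8 in every M82 plant and below 4 in every IL7-3 plant.

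A second reading of the same question compares probes by detection alone. In both scans of all 6 M82 plants, 9 probes were above the limit that were below it in both scans of all 5 IL7-3 plants, and 1 probe showed the opposite arrangement. Of these 9 probes, 7 were among the 40 lower ones.

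Within the 2007 trial, 8 probes were lower and 1 was higher in IL7-3 (3 against 2 plants, limma adjusted p below 0.05), 6 and 0 with scaling to the 75th percentile, and 9 and 0 with cluster membership as a term. The 1 higher probe was again TC174512_736_39, named here because its count is small and after its values had been seen. It was below the detection limit in all 3 M82 plants of 2007 and at least 12.0-fold higher in IL7-3. For its fitted difference the limma adjusted p was 0.029, 0.0502 with cluster membership as a term, and 0.45 with only the plants of that year in the fit. Of the 11 fits without 1 plant it kept the threshold in 2, those without IL7-3 replicate 1 of 2007 and without M82 replicate 5 of 2008, with adjusted p up to 0.18. It was at least 24.99-fold higher without IL7-3 replicate 1 of 2007 and at least 5.78-fold higher without IL7-3 replicate 2 of 2007. The count of 9 became 4 without M82 replicate 2 of 2007, 4 without IL7-3 replicate 1 and 3 without IL7-3 replicate 2 of that year, and 18 without M82 replicate 5 of 2008.

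Within the 2008 trial, 17 probes were lower and 1 was higher in IL7-3 (3 against 3 plants), 10 and 2 with cyclic loess, and 16 and 1 with cluster membership as a term. The higher probe, TC172859_558_40 (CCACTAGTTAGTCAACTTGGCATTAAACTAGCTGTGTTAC), named here after its values had been seen, had a log2 intensity of 4.40 ± 0.30 (SD, n = 3) in M82 and 7.91 ± 0.92 (SD, n = 3) in IL7-3. It was below the limit in all 3 M82 plants and in 1 IL7-3 plant, and at least 1.11-fold higher in IL7-3. The probe passed the threshold by its fitted log2 difference of 3.51 (limma adjusted p = 0.017), which rests on values below the limit, and not by that bound. It lost the threshold without M82 replicate 6, or IL7-3 replicate 5 or 6, of 2008, with adjusted p up to 0.13. Its adjusted p was 0.027 with cluster membership as a term, 0.17 with scaling to the 75th percentile, 0.21 with only the plants of that year in the fit, 0.28 in the high scans and, the highest of 27 alternatives, 0.9996 from the authors' value table. The count of 18 became 31 without M82 replicate 4, 28 without M82 replicate 5, 10 without IL7-3 replicate 4, 6 without IL7-3 replicate 5 and 7 without IL7-3 replicate 6.

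The trials share no plants, but both sets of calls come from 1 fit with 1 spread estimate per probe; with only a year's own plants in the fit, 1 probe passed in 2007 and 9 in 2008. Of the 9 probes called in 2007, all 9 differed in the same direction in 2008 and 8 were called there too. Of the 18 called in 2008, 17 differed in the same direction in 2007 and 16 did so with an unadjusted p below 0.05. Over all 20201 probes the correlation between the line differences of 2007 and 2008 was 0.0298, a value across probes, which are not independent replicates. The difference of the line effect between years, tested as an interaction in limma, passed the threshold for 0 probes, with 1355 probes at an unadjusted p below 0.05. Without M82 replicate 5 of 2008 it passed for 4 probes.

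**Figure D3:**
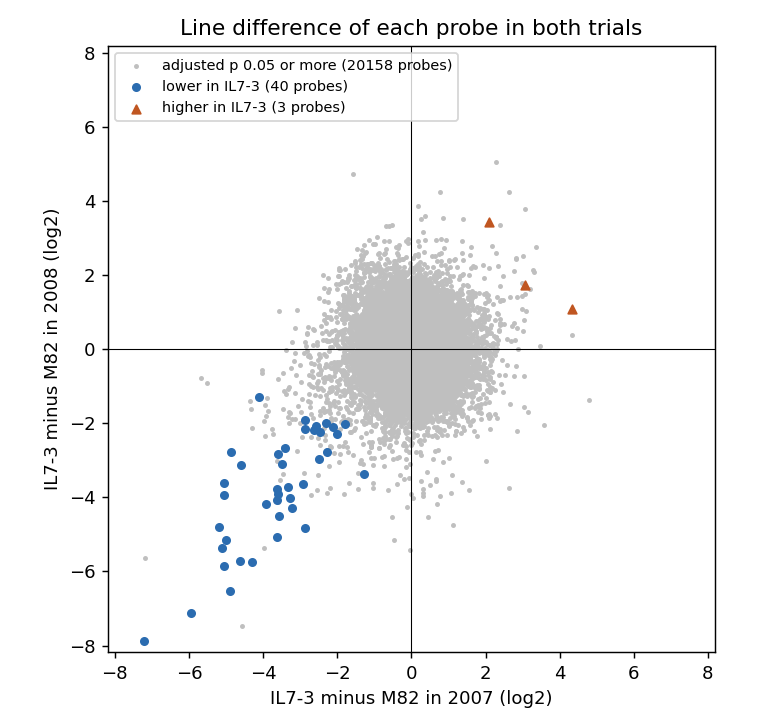
Log2 difference between IL7-3 and M82 of each probe in 2007 (horizontal) and 2008 (vertical), with 40 probes lower in IL7-3 as blue circles, 3 higher as orange triangles and 20158 others in grey. The 40 lower probes, picked by the mean of both differences, all lie below 0 on both axes, and over all 20201 probes the correlation is 0.0298.

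Between the years, with both lines averaged, 0 probes were lower and 1 was higher in 2008 than in 2007 in limma, and 1914 probes had an unadjusted p below 0.05. The probe was TC172859_558_40 again, at 2.94 ± 0.10 (SD, n = 3) in M82 and 3.20 ± 0.04 (SD, n = 2) in IL7-3 in 2007, all below the detection limit, as were all 3 M82 plants of 2008. No fold is given for it (limma adjusted p = 0.049). It kept the threshold in 2 of the 11 fits without 1 plant, those without IL7-3 replicate 2 of 2007 and without IL7-3 replicate 4 of 2008, and the adjusted p over the 11 fits reached 0.49. With cluster membership as a term, 0 probes passed and 444 had an unadjusted p below 0.05. The small cluster lies wholly in 2007, and without IL7-3 replicate 2 of 2007, which belongs to the larger cluster, 85 probes were higher and 16 lower in 2008.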

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

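The split counts for the fits without a cluster term and for the excess of lower probes, the detection count, the tests of scaling or brightness, of donor allele mismatch and of transcript level, and all tests of the 3-plant cluster and of the strand were chosen after the result was seen; the split count of calls with the cluster term and the scan test were set down before their results.

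Signal appeared in probes outside the main measurement. Of the 42 spike probes, 5 lay above the negative control limit in 20 or more of the 22 scans. Of the 19 factory probes that are not negative controls, 2 lay above it in all 22 scans. M82 replicate 5 of 2008 had 2 to 3 spike probes above the limit, and the other 10 plants had 6 to 12.

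The count of line calls (40 lower and 3 higher in IL7-3) and its excess of lower probes were set against chance first. Of 100 splits of the plants within years, 12 gave as many calls as the 43 of the real split, which is 1 of the 12, and the highest other gave 371, so chance is not excluded for the count without a cluster term. The other 11 splits were those that put the 3 plants of the small cluster on one side, which points to that structure. With cluster membership as a term, the 100 splits were drawn from the 180 of 200 in which the term could be estimated. That leaves out every split with the 3 plants of the small cluster on one side, the kind that gave the highest counts without the term. Among the drawn splits, 1 of 100, the real one, reached its 45 calls, and the highest other gave 12. Chance is thus excluded only against splits without that structure, and the term was defined from these data. The excess of calls in one direction was as large as the 37 of the real split in 12 of 100 splits without the term, with 298 as the highest other, so chance is not excluded. With the term the excess was as large as 35 in 1 of 100, the real one, with 10 as the highest other. Chance is excluded there only against the same restricted set of splits. By detection alone, 2 of the 462 splits of the 11 plants, the real one among them, gave as many probes as the real split's 10. Chance is excluded for that count only where plants are exchanged freely across years and clusters, since these splits hold neither fixed. The highest other split also gave 10, all in one direction, and has the 3 plants of the small cluster on one side. A grouping other than the lines can thus give as many such probes. For 2008 alone the 10 possible splits are too few for a share under 0.05; the real split gave 18 calls and the highest other 0. For the years, 4 of 100 splits gave as many as the 1 call of the real split and the highest other gave 3; of all 200 splits 6 did, a share that excludes chance for the count of 1 taken alone. These splits take no account of the small cluster, which lies wholly in 2007; with the cluster term the count is 0, and the call was lost in 9 of the 11 fits without 1 plant, so nothing is built on it.

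Scaling or brightness was tested as the cause of the excess of lower probes in IL7-3. Without normalization, the 2000 uncalled probes nearest to the lower probes in M82 brightness had a median log2 difference of 0.63 (SE 0.28 over plants). That is less than the smallest fitted fall of 1.91, a mild yardstick, since it comes from probes picked for their falls. Of these, 25 were below the detection limit in all IL7-3 plants. Normalization removes that difference, which lowers IL7-3, but without it all 40 lower probes were still lower in IL7-3, and 10 probes were called lower and 0 higher. The 40 probes were picked for falls larger than that difference, so their staying lower was likely from the start. The matched probes show something narrower: uncalled probes of like brightness shared no fall without normalization, with quartiles of 0.35 and 0.89. Whether scaling or brightness adds to the falls of single probes is not decided. The number of lower calls depends on the normalization. For the 40 lower probes, a base mismatch between the donor allele and a probe made for the cultivated allele and a lower transcript level in IL7-3 cannot be told apart, because 0 of the probes could be placed on a genome and no donor sequence was used. The biological reading therefore stays a hypothesis.

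The cluster of 3 plants spans both lines but leaves out a 2007 plant of each line. A candidate explanation is a labelling batch in which the amplification primer left a different leader sequence on every antisense RNA molecule, so that probes complementary to the leader light up in one batch only. In the odd-numbered probes, the 6 bases with the lowest mean difference between the 3 plants and the larger cluster were GCCTCC (-4.05 over 32 probes), and in the even-numbered probes, not used to find it, its 39 carriers had a mean log2 difference of -4.69 (SE 0.41). Base composition alone is argued against, as GCCTCC lay -3.74 SD from the mean of the 28 other orderings of its bases in the even-numbered probes, the lowest of which reached -4.45. Fruit that differed between these plants for other reasons was not tested and stays open beside the batch. Of the 43 line calls, 0 carried one of the cluster sequences, but only 256 of all 20201 probes carry one. So small a share would leave few or none among the calls by chance, and the 0 does not show that the calls are free of the batch.

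M82 replicate 5 of 2008 stood apart from all other plants. A fault of 1 scan is argued against, since its deviation from the larger cluster correlated with r = 0.82 between its high and low scans. Labelling of the opposite strand stays open: probes with GCCTCC were lower in this plant (-1.35 over 71 probes) and those with its reverse complement GGAGGC higher (0.70 over 99 probes), but only 79.3% of the 29 other orderings of these bases had a lower mean, short of the 95% set as the bound. Over bright probes, this plant's median coefficient of variation over spots was 0.207 in the high scan and 0.212 in the low scan, the highest of all plants. Array quality was not tested as a cause, and no biological explanation was tested for a single plant.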

How the results depend on the processing

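No alternative reversed the direction of a named probe. Over 28 alternatives each, TC177079_695_40 and TC170138_289_39 kept their fall past the threshold in all 28, each with an adjusted p up to 0.0081. The dim probe filter removed both of them and TC172859_558_40, so it is not among the alternatives of these probes. The rises of TC170110_850_39, TC174512_736_39 and TC177287_1174_40 kept it in 12, 19 and 13 of 29 alternatives, with adjusted p up to 0.31, 0.22 and 0.23. In 2007 alone TC174512_736_39 kept it in 10 of 28, and TC172859_558_40 kept it in 16 of 27 for 2008 alone and in 6 of 26 for the year. The cause was not tested unless named.

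The line count of 43 stayed within 1.5 times in 21 of 30 alternatives. Among these, the minimum log2 difference of 1 could not change it, since the smallest called difference was 1.91. A like count need not mean the same probes: of the 33 called with the dim probe filter, 23 were among the 43. The count was 11 with background correction from negative controls, 17 from the authors' value table, 77 with array weights and 22 in the larger cluster alone, which has fewer plants. Without 1 plant it ran from 15 to 55. In 2007 the count of 9 became 14 in the low scans, 1 with that background correction, 2 with the dim probe filter, 3 from the value table, 1 with only the plants of that year in the fit, 0 in the larger cluster and 20 with the cluster term without M82 replicate 5 of 2008; without 1 plant it ran from 3 to 18. In 2008 the count of 18 became 10 in the high scans, 11 with 75th percentile scaling, 3 with background correction, 1 with the dim probe filter, 6 from the value table, 9 with only that year's plants, 64 with array weights and 30 with the cluster term without replicate 5; without 1 plant it ran from 6 to 31. The interaction count of 0 became 4 with the cluster term without replicate 5, and ran from 0 to 4 without 1 plant. The year count of 1 became 0 in the high scans, the low scans, 75th percentile scaling, cyclic loess, background correction, the dim probe filter, the median of spots, the value table, the additive model, the cluster term, the larger cluster and that term without replicate 5; without 1 plant it ran from 0 to 101.

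Scaling to the 75th percentile moved the median of all probes by 0.11 (line), 0.10 (2007), 0.095 (2008) and 0.28 (year) on the log2 scale; the value table moved it by 0.32 in 2007. Lower probes were at least 80.0% of the line calls, the lowest share being that without M82 replicate 4 of 2008, with 11 of 55 higher.

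With the replicate number as a block, the line count was 14, all lower, the 2007 count 0, the 2008 count 7 and the interaction count 0; own numbers correlated best in 1 of 5 pairs, so the block is no pairing. The year could not be fitted with that block, since numbers are nested in years. Gene list and chromosome 7 tests were not run, for lack of names and positions, nor was a slide or scan date block, since the files give none.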

Other observations

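The authors' value table holds, in the column of the low scan of M82 replicate 6 of 2008, the values of that plant's high scan up to 1 constant. The other columns that do not match their own scanner file are the high scan of IL7-3 replicate 1 of 2007 and the low scans of IL7-3 replicates 5 and 6 of 2008. Counts from that table are therefore not independent of a mix-up of columns, and the scanner files were preferred for the main values.

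The probes with the highest mean difference in the small cluster did not repeat: the 6 bases with the highest mean in the odd-numbered probes, TGCGGA, had a mean log2 difference of 0.67 over 27 probes there and -0.14 (SE 0.20) over 32 even-numbered probes.

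The array weights estimated by limma ranged from 0.22 for M82 replicate 5 of 2008 to 3.31 for IL7-3 replicate 6 of 2008.

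Of the 40 probes lower in IL7-3, 7 were above the detection limit in all 5 IL7-3 plants and 21 were above it in all 6 M82 plants. The mean normalized log2 intensity of the 40 probes in M82 ran from 4.80 to 12.67, with a median of 9.36, and in IL7-3 from 2.42 to 10.31, with a median of 5.27.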
